A study of Arabidopsis thaliana with 60 samples.

How the data were processed

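Polyadenylated RNA of 60 Arabidopsis thaliana leaf samples was measured: 2 treatments (Pseudomonas syringae pv. tomato DC3000 avrRpm1, mock), 2 areas of the same leaves (IN, infiltrated; OUT, immediately adjacent), 5 times (0, 1, 2, 4 and 6 h) and 3 replicates from independent experiments, each of 6 leaves from 3 plants. The deposited table holds 1 signal value per gene and library, which the authors made as normalized counts: read counts divided by scaling factors. Per the labels the tools were FastQC, Trim Galore, Salmon 0.11.3 and DESeq2 with the TAIR10 genome; their order and any filter are not given. The values are not whole numbers. Low values cluster near multiples of a step per library, and 53.9 to 82.6% of the values up to 5 reads lay within 0.1 of a whole multiple, so whole reads could not be recovered and no count model was run. The normalized counts of a library summed to between 19761604 and 28566398 (median 22896667); as scaled values these sums do not measure depth. Dividing each by the step of its library gave an estimated 15150000 to 34050000 reads (median 22790000). Chloroplast transcripts held 0.047 to 0.419% of the normalized counts and mitochondrial transcripts 0.0029 to 0.0412%. With such depth, genes near the minimum of 10 are the ones measured least precisely.

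The table held 23986 identifiers: 23555 nuclear loci, 103 chloroplast, 100 mitochondrial and 228 others. Gene names were taken from the TAIR10.1 annotation, in which all 23555 nuclear loci were found; no coordinates were used. Genes with at least 10 in at least 3 libraries were tested (20560). Values were analysed as log2(value + 1), which understates the change of low genes. R 4.3.3 with limma 3.58.1 fitted 20 group means to the 60 libraries, with empirical Bayes moderation using a mean trend and robust settings. Infected was compared with mock at each time in each area, and mock at each later time with mock at 0 h, with an F-test over the 4 later times. The difference between the areas was tested on IN minus OUT within each of the 30 leaf pools, since both came from the same leaves. The mock area difference was averaged over the 5 times. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

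Gene lists, comparisons, alternatives and the rule for naming genes were chosen before the data were examined. The 22 lists (400 members, 1 dropped because its symbol belongs to another locus, 396 tested) cover salicylic acid, jasmonate, ethylene, early immune response, intracellular receptors and cell death, tryptophan and camalexin, oxidative stress and detoxification, wound and touch, abscisic acid, auxin response, endoplasmic reticulum protein folding, heat shock, autophagy, photosynthesis, aliphatic glucosinolates, phenylpropanoids and flavonoids, circadian clock, markers of guard cells, phloem, xylem and epidermis, and reference genes. They were written from general knowledge of the genes and tested with limma's camera at a preset correlation of 0.01, and again with a correlation estimated for each list, over 110 tests per family. Genes named are, per time and area, the 4 largest rises and 4 largest falls past the threshold with all 3 values of a group above all 3 of the other and a mean of at least 50 in the higher group; 3 each way for the difference between areas; up to 4 members with the largest changes of each list described; the 10 leading genes confined to IN, by the smaller of the 4 and 6 h rises, and 5 leading genes of the surrounding area; and a fixed set of 10 genes that includes PR1, ICS1, PAD3, FRK1, RPM1, RIN4, JAZ10, AT5G17760, ACT2 and UBQ10.

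Replicate letters stand for the 3 experiments. After group means were removed, IN and OUT libraries of the same letter correlated at a mean of 0.362 across genes, 26 of 30 pairs above 0.1. Infected and mock libraries of the same letter correlated at 0.188, and those of any 2 different groups at 0.079. The means for other letters (-0.178, -0.093 and -0.038) follow largely from removing means of 3 libraries, so they are no separate comparison. A replicate block was therefore tried as an alternative, along with other pseudocounts, no filter, quantile normalization, rescaling to the same upper quartile, plain empirical Bayes, a fit to the libraries compared alone, subtraction of the difference at 0 h, unpaired areas and leaving out each library. Groups of 3 are too small for a rule on single outlying values. The steps were tested on simulated data made from these values: of genes changed 4-fold, 69.7% were recovered in IN at 4 h, 77.3% in OUT at 6 h, 59.1% for the area difference at 4 h and 95.5% between the mock areas. In the same order 51.5, 43.9, 30.3 and 83.3% were recovered of genes changed 2-fold, and 20.6, 25, 0 and 52.9% of genes changed 1.5-fold. Of the calls, 6 of 100, 3 of 100, 1 of 60 and 5 of 159 were unchanged genes. Each simulation changed 68 genes 1.5-fold, 66 genes 2-fold and 66 genes 4-fold, of 20560, and drew the libraries independently. In the real comparisons far more genes passed and libraries of the same letter correlated. These shares therefore do not give the recovery or the false calls there.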

Results

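Leaves of Arabidopsis thaliana accession Columbia-0 were infiltrated over part of the blade with Pseudomonas syringae pv. tomato DC3000 carrying the effector gene avrRpm1, or with a mock solution. In this accession the intracellular receptor RPM1 recognises the effector's action on its host target RIN4 and starts a hypersensitive response, a defence in which the infected cells die. Tissue inside the infiltrated area (IN) and tissue immediately next to it (OUT) was collected at 0, 1, 2, 4 and 6 h after infiltration. The 2 treatments, 2 areas and 5 times gave 20 groups of 3 libraries of polyadenylated RNA, replicates A, B and C coming from 3 independent experiments, so 60 libraries in all. Each sample pooled 6 leaves of 3 plants. The normalized counts of a library summed to between 19761604 and 28566398 (median 22896667), and the depth was estimated from the step between low values at 15150000 to 34050000 reads (median 22790000). Of 23986 genes and other transcribed loci in the table, 20560 were tested. Group values below are mean normalized counts ± SD over 3 libraries, log2 fold changes of log2(value + 1) are given ± SE, and adjusted p-values come from limma unless camera, a test of gene lists, is named. Where infected is compared with mock, rose and fell mean higher and lower than mock at the same time, not a change since 0 h. Changes given there from 1 value to another run from mock to infected tissue.

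Time, infection and area all separated libraries on the first 2 principal components. At 1 h mock IN libraries lay at 50 to 51.4 on the first and mock OUT libraries at -35.6 to -23.1. The first principal component held 41.43% of the variance and the second 17.61%. Within groups, libraries correlated at 0.921 to 0.986 across genes. At 2 h, 2 mock libraries, singled out after their values were seen, lay apart from their groups. On a score built from genes that differed between the mock areas at the other times after infiltration, mock IN replicate A stood at 0.379 against 3.87 and 3.29 for replicates B and C, and mock OUT replicate B at 3.49 against 0.444 and 0.293 for replicates A and C.

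**Figure D1:**
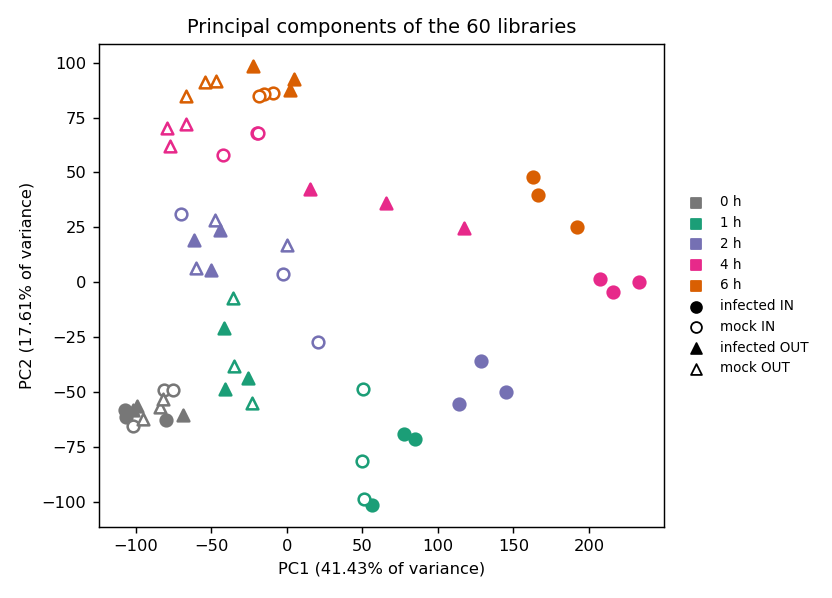
Principal components of the 60 libraries, with PC1 (41.43% of the variance) on the x axis and PC2 (17.61%) on the y axis. Each point is 1 library, coloured by time, filled for infected and open for mock, circles for IN and triangles for OUT. Infected IN libraries at 4 and 6 h lie at the highest PC1 (162.7 to 232.9), and PC2 runs from at most -49.0 in mock libraries at 0 h to at least 84.8 at 6 h.

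Camera called 51 of 110 list tests in IN, 28 of 110 in OUT and 37 of 110 for the difference between the areas, and 0 in each with an estimated correlation. At 0 h, when no gene passed, camera called 7 lists in IN and 3 in OUT. Among them was the salicylic acid list in IN (median -0.57, camera adjusted p = 1.25e-05, adjusted p = 0.556 with an estimated correlation). The counts of members beside each call therefore carry the weight, read against all tested genes. Of these, 2.9, 46.9, 69.2 and 59.1% passed in IN at 1, 2, 4 and 6 h, and 42.2 and 5.2% in OUT at 4 and 6 h. For the area difference 2.05, 49.9, 46.8 and 47.9% passed at 1, 2, 4 and 6 h. Calls split nearly evenly between higher and lower, except at 1 h and in OUT at 6 h, where most were higher. Counts near these shares do not set a list apart.

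The first comparison asked how infected IN tissue differed from mock IN tissue at each time. At 0 h no gene passed limma's test, with 347 genes at an unadjusted p under 0.05. By 1 h, 512 genes were higher and 85 lower. The largest rises were in the phloem protein gene PP2-B13 (AT1G56240; log2 fold change 5.17 ± 0.81, adjusted p = 9.24e-05), with 1467 ± 188 in infected against 81.0 ± 109 in mock tissue. Next came the cytochrome P450 gene CYP82C3 (AT4G31950; 4.89 ± 0.87, adjusted p = 0.000465), the F-box gene AT4G22030 (4.83 ± 0.90) and the NAC transcription factor gene AT3G12910 (4.82 ± 0.79). PP2-B13 has a close copy, PP2-B14, with which reads may be shared. The largest falls were in the RING-type gene ATL15 (AT1G22500; -2.08 ± 0.53), the homeobox gene HB-12 (AT3G61890; -1.86 ± 0.44), the dehydrogenase gene AT5G16980 (-1.85 ± 0.45) and MYB95 (AT1G74430; -1.71 ± 0.49). Of 26 genes of the early immune response, 9 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 1.26. Among them CYP81F2, of indole glucosinolate metabolism, rose by 3.80 ± 0.67, the peroxidase gene PER4 by 3.18 ± 0.85 and MYB51, a regulator of indole glucosinolates, by 3.01 ± 0.60. WRKY30 missed the threshold (2.77 ± 0.84, adjusted p = 0.0596). Camera called the list higher (adjusted p = 2.94e-15, adjusted p = 0.199 with an estimated correlation). Among 31 jasmonate genes 0 rose and 2 fell, the same as adjusted over the list alone. JAZ2, a repressor of jasmonate responses, fell by 1.44 ± 0.33 on the log2 scale, and the list was called lower (camera adjusted p = 2.11e-07, adjusted p = 0.556 with an estimated correlation). Of the genes named at 1 h, AT4G22030, MYB51, JAZ2, HB-12, ATL15, AT5G16980, MYB95 and PER4 missed the threshold without mock replicate B, AT5G16980 falling to -0.96 (adjusted p = 0.415). Without infected replicate A, JAZ2, HB-12, ATL15, MYB95 and PER4 missed it, without infected replicate C JAZ2, HB-12, AT5G16980, MYB95 and PER4, without infected replicate B ATL15 and PER4, without mock replicate A ATL15, MYB95 and PER4, and without mock replicate C MYB95. In these fits, each with 1 library fewer, the folds of PER4 (2.37 to 3.48), ATL15 (-2.14 to -1.75), JAZ2 (-1.36 to -1.21), HB-12 (-1.79 to -1.54) and MYB95 (-1.88 to -1.48) stayed nearer to those of all libraries than did MYB51 (1.80) and AT4G22030 (3.13) without mock replicate B. PER4 also missed the threshold with a pseudocount of 0.5 (adjusted p = 0.0535) and MYB95 without the filter (adjusted p = 0.0502) and under plain empirical Bayes (adjusted p = 0.0514). WRKY30 passed without mock replicate C (3.24, adjusted p = 0.0448) and with a pseudocount of 5 (2.77, adjusted p = 0.0292). The count of 597 genes moved with single libraries and with the shared estimate of spread. It was 197 without mock replicate B, 269 without infected replicate A, 273 without infected replicate C, 110 after the difference at 0 h was subtracted, and 0 (2620 at an unadjusted p under 0.05 in the fit to all groups) when limma used only the 6 libraries compared.

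At 2 h, genes of immune perception and signalling rose together in infected IN tissue. All 26 early immune genes rose (26 adjusted over the list alone; median 4.31). PER4 rose from 14.1 ± 7.56 to 3403 ± 580 (7.98 ± 0.86, adjusted p = 3.76e-10), NHL10 by 6.97 ± 1.03 and the MAP kinase gene MPK11 by 5.83 ± 0.62. FRK1, a receptor-like kinase gene induced by bacterial flagellin, rose from 611 ± 672 to 15090 ± 3551 (5.36 ± 0.99, adjusted p = 2.1e-05). Of 21 genes of intracellular immune receptors and cell death, 20 rose and 0 fell (20 and 0 adjusted over the list alone). They included BON1, BAP1 and BAP2, whose products hold back cell death (4.12 ± 0.31, 4.01 ± 0.45 and 4.72 ± 0.77), and the metacaspase gene MC2 (3.74 ± 0.65). The receptor gene RPM1 and its partner rose too, RPM1 (AT3G07040; 1.96 ± 0.26, adjusted p = 6.45e-08) and RIN4 (AT3G25070; 1.33 ± 0.16, adjusted p = 9.25e-09). Camera called the early immune list (adjusted p = 6.88e-17, adjusted p = 0.199 with an estimated correlation) and the receptor list (adjusted p = 1.19e-10, adjusted p = 0.199 with an estimated correlation) higher.

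Salicylic acid and ethylene genes rose at the same time. Among 25 salicylic acid genes, 14 rose and 1 fell (16 and 1 adjusted over the list alone). The transcription factor genes CBP60G and SARD1 rose by 5.90 ± 0.54 and 4.05 ± 0.61, PBS3 by 4.45 ± 0.52 and PAD4 by 3.88 ± 0.53. ICS1 (AT1G74710), which encodes the isochorismate synthase of salicylic acid synthesis, rose by 3.44 ± 0.48 (adjusted p = 1.51e-07). Of 20 ethylene genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone), led by the ethylene synthesis gene ACS7 (5.85 ± 0.98) and the response factor gene ERF2 (4.81 ± 0.70). Of 14 wound and touch genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone), the calmodulin-like gene CML37 by 6.05 ± 0.63. Of 17 genes of protein folding in the endoplasmic reticulum, 13 rose and 0 fell (17 and 0 adjusted over the list alone), among them BZIP60 (2.83 ± 0.37) and BIP2 (2.31 ± 0.56), though only 6 rose after quantile normalization. For these lists camera gave adjusted p = 2.55e-05 (salicylic acid; adjusted p = 0.556 with an estimated correlation), 3.79e-05 (ethylene; adjusted p = 0.265 with an estimated correlation), 0.000251 (wound and touch; adjusted p = 0.556 with an estimated correlation) and 0.000534 (protein folding; adjusted p = 0.627 with an estimated correlation). Oxidative stress, jasmonate, camalexin and phenylpropanoid genes had begun to rise, with 16 of 26, 13 of 31, 13 of 17 and 11 of 18 higher (16, 13, 13 and 11 adjusted over the list alone).

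Photosynthesis genes fell at 2 h. Of 47, 35 fell and 0 rose (38 and 0 adjusted over the list alone; median -0.76), PORB, of chlorophyll synthesis, by 1.78 ± 0.49 on the log2 scale. Among 12 genes of aliphatic glucosinolates, 8 fell and 0 rose (9 and 0 adjusted over the list alone), including the regulator genes MYB29 (-2.12 ± 0.49) and MYB28 (-1.74 ± 0.44). Camera called both lower (adjusted p = 6.77e-08 and 0.0025, adjusted p = 0.59 and 0.627 with an estimated correlation). Over all genes, 4914 were higher and 4720 lower. The largest rises were in PP2-B14 (AT1G56250; 8.66 ± 0.73), the matrix metalloproteinase gene MMP (AT1G70170; 8.503 ± 0.718), PP2-B13 (8.12 ± 0.81) and PER4. The largest falls were in AT5G66580 (-4.22 ± 0.62), AT3G08660 (-3.92 ± 0.55), GDU4 (-3.74 ± 0.82) and GIS (-3.71 ± 0.63). Quantile normalization turned the split to 3871 higher and 6022 lower, rescaling to the same upper quartile to 3742 and 6757. The fit to the 6 libraries alone called 6209 genes. Without both mock libraries that lay apart at 2 h, a choice made after the data were seen, 7413 genes passed.

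At 4 h the IN response had spread to 14225 genes, 7143 higher and 7082 lower. The even split rests on the scaling as deposited. The median of all genes was 0.016 as deposited, -0.129 after quantile normalization and -0.248 with the same upper quartile. Mitochondrial transcripts held 0.0222, 0.0412 and 0.0115% of the normalized counts in infected IN replicates A, B and C at 4 h, against 0.0052, 0.0066 and 0.0057% in mock IN tissue. Chloroplast transcripts were higher too, at 0.219, 0.232 and 0.1% against 0.089, 0.097 and 0.061%. That share also varied elsewhere, up to 0.419% in mock OUT replicate A at 2 h. All 26 genes of oxidative stress and detoxification rose (26 adjusted over the list alone; median 5.04), among them the alternative oxidase gene AOX1D (AT1G32350). It went from 5.98 ± 3.83 to 3736 ± 1045 (9.21 ± 1.33, adjusted p = 6.49e-08). The glutathione transferase genes changed likewise, GSTU11 (7.90 ± 0.90), GSTU24 (7.33 ± 0.77) and GSTU2 (7.14 ± 0.76). Of 12 heat shock genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone; median 5.80), with small chaperone gene AT1G52560 at 599 ± 526 against 1.18 ± 1.09 (7.14 ± 0.96), HSP17.6A (6.81 ± 1.38) and the heat stress factor gene HSFA2 (6.44 ± 0.89). Of 17 tryptophan and camalexin genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone). PAD3 (AT3G26830), the enzyme gene of the last step to the phytoalexin camalexin, stood at 50120 ± 8274 against 178 ± 115 (8.44 ± 1.22, adjusted p = 6.93e-08). The transporter gene ABCG40 stood at 123700 ± 33950 against 96.6 ± 22.8 (10.30 ± 0.99). Camera called the 3 lists higher, with adjusted p = 9.78e-09, 0.00135 and 8.16e-05 (adjusted p = 0.199, 0.557 and 0.556 with an estimated correlation).

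Jasmonate and abscisic acid genes were widely higher at 4 h. Of 31 jasmonate genes, 30 rose and 1 fell at 4 h (30 and 1 adjusted over the list alone; median 3.099), including CYP94B3, which hydroxylates active jasmonate (5.66 ± 0.80), the synthesis genes AOC3 (5.46 ± 0.63) and LOX4 (5.22 ± 0.64), and JAZ10 (AT5G13220; 4.09 ± 0.68, adjusted p = 1.04e-06). Of 22 abscisic acid genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), led by the phosphatase genes HAI1 (9.17 ± 0.86) and HAI2 (6.41 ± 0.58) and the transcription factor gene RD26 (6.67 ± 0.53). Both lists were called higher (camera adjusted p = 6.97e-06 and 2.55e-05, adjusted p = 0.556 for both with an estimated correlation). Phenylpropanoid and flavonoid genes rose in 13 of 18 cases (13 adjusted over the list alone; camera adjusted p = 0.0033, adjusted p = 0.556 with an estimated correlation), among them PAL2 (4.64 ± 0.41) and C4H (4.04 ± 0.43). Of the salicylic acid genes 13 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.0283, adjusted p = 0.767 with an estimated correlation), with FMO1 and ALD1, both of systemic immunity, higher by 7.21 ± 1.48 and 6.931 ± 1.097. PR1 (AT2G14610), a late salicylic acid marker, varied widely within groups and passed the test at no time (at 6 h 2076 ± 918 against 666 ± 776, 3.11 ± 2.42, adjusted p = 0.27). RPM1 had turned lower (-0.67 ± 0.26, adjusted p = 0.0238), a call lost without infected replicate B (-0.47, adjusted p = 0.159) or mock replicate A or B. The ATPase gene AT5G17760 stood at 6421 ± 1118 against 626 ± 65.9 (3.35 ± 0.34, adjusted p = 2.16e-11).

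All 47 photosynthesis genes fell at 4 h (47 adjusted over the list alone, median -1.92). RBCS1B, a small subunit gene of Rubisco whose reads may be shared with its copies, stood at 4264 ± 2819 against 43920 ± 8011 in mock tissue (-3.57 ± 0.35). PRK, of the Calvin cycle, fell from 27810 ± 2388 to 3234 ± 996 (-3.15 ± 0.27). Of the aliphatic glucosinolate genes 11 fell and 0 rose (0 higher and 12 lower adjusted over the list alone), with MYB28 at -4.74 ± 0.44. Camera called them lower with adjusted p = 2.94e-15 and 0.000344 (adjusted p = 0.556 and 0.566 with an estimated correlation). Among 10 auxin genes, 5 rose and 5 fell (5 and 5 adjusted over the list alone), with GH3.3 higher (4.23 ± 0.70) and the auxin transport genes PIN7 (-4.76 ± 0.42) and PIN3 (-3.56 ± 0.34) lower; camera did not call the list (adjusted p = 0.778). The largest rises of single genes were in WRKY67 (AT1G66550; 3908 ± 1657 against 0.453 ± 0.785, 11.43 ± 0.74), DIN11 (AT3G49620; 2837 ± 1971, listed at 0 in all 3 mock libraries), BGLU27 (AT3G60120; 10.93 ± 1.06) and the bHLH factor gene AT2G22760 (10.43 ± 0.74). The largest falls were in the expansin gene EXPA8 (AT2G40610; 7.46 ± 11.9 against 1131 ± 711, -7.974 ± 1.012), AT5G02760 (-6.67 ± 0.80), the auxin-response gene AT1G29430 (-6.49 ± 0.64) and AT1G52190 (-6.47 ± 0.65). Of 12 reference genes often used to normalize, 5 were higher and 2 lower as deposited (5 and 2 adjusted over the list alone), and 3 were higher and 5 lower after quantile normalization. UBQ10 was higher (1.70 ± 0.20). ACT2 was not called as deposited (0.27 ± 0.16, adjusted p = 0.134) and was lower after quantile normalization (-0.45, adjusted p = 0.00543).

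At 6 h, 6028 genes were higher and 6126 lower in IN, where mitochondrial transcripts held 0.0092 to 0.0135% in infected against 0.0057 to 0.0077% in mock libraries. This split, too, rests on the scaling. The median of all genes was -0.003 as deposited, -0.081 after quantile normalization and -0.141 with the same upper quartile. Of the genes higher at 4 h, 5278 were also higher at 6 h, where independent lists would share 2094, and 5265 were lower at both (2110). Photosynthesis genes were again all lower (47, and 47 adjusted over the list alone; median -2.21), the Calvin cycle genes FBA1 by 3.47 ± 0.26 and SBPASE by 2.99 ± 0.23 on the log2 scale. Oxidative stress genes remained higher in 25 of 26 cases (25 adjusted over the list alone), GSTU25 by 8.54 ± 0.96 and the glucosyltransferase gene UGT74E2 by 7.70 ± 0.92. Heat shock genes were higher in 11 of 12 (11 adjusted over the list alone), HSP17.6A by 7.48 ± 1.38 and HSP17.4 by 7.30 ± 1.44. Autophagy genes rose in 13 of 17 cases with 1 lower (13 and 1 adjusted over the list alone), including ATG8H (3.20 ± 0.26) and ATG7 (1.65 ± 0.16). Camera gave adjusted p = 1.94e-24, 3.07e-09, 0.000251 and 0.000345 for these lists (adjusted p = 0.353, 0.199, 0.556 and 0.556 with an estimated correlation). Of 8 epidermis markers 1 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0408, adjusted p = 0.586 with an estimated correlation), the cuticle transporter gene CER5 by 1.74 ± 0.20 on the log2 scale. Guard cell, phloem and xylem markers were not called in IN between 1 and 6 h; at 6 h 1, 2 and 2 of 6, 8 and 7 were higher and 1, 3 and 1 lower (1, 2 and 0 higher and 1, 3 and 1 lower adjusted over the list alone), with camera adjusted p = 0.977, 0.888 and 0.635. The largest rises were in DIN11 (10.45 ± 1.24), the NADPH oxidase gene RHD2 (AT5G51060; 9.55 ± 0.81), UGT73B4 (AT2G15490; 9.18 ± 0.94) and AT3G49540 (8.81 ± 0.62). The largest falls were in the protease gene AT2G27420 (-6.005 ± 0.793), the ethylene synthesis gene ACS4 (AT2G22810; -5.78 ± 0.83), AT5G36790 (-5.50 ± 0.81), which has a near-identical copy, and AT2G27402 (-5.25 ± 0.91).

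**Figure D2:**
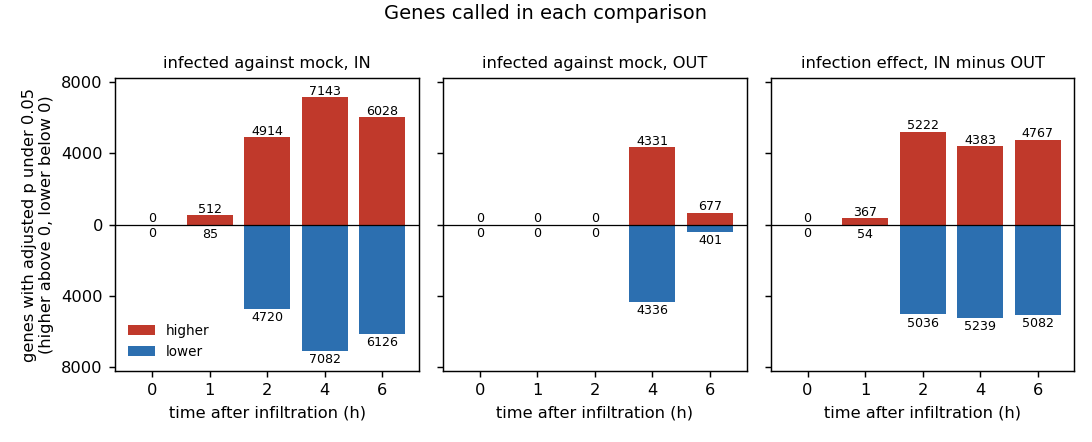
Genes past an adjusted p of 0.05 in limma, higher (red, above 0) and lower (blue, below 0), on the y axis against hours after infiltration on the x axis, for infected against mock in IN and in OUT and for the difference of the 2 effects. IN calls rise from 0 at 0 h to 14225 at 4 h, while OUT calls appear only at 4 h (8667) and 6 h (1078).

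The second comparison asked what happened in the OUT tissue, which was not infiltrated. No gene passed limma's test at 0, 1 or 2 h, with 205, 351 and 225 genes at an unadjusted p under 0.05. Each count is less than 0.05 of the 20560 genes tested, the share expected without any effect. The same holds at 0 h for IN (347) and for the area difference (254). The test may therefore be strict in these comparisons, and a lack of calls does not show that nothing changed. At 4 h, 4331 genes were higher and 4336 lower. Jasmonate genes led, as 29 of 31 rose and 0 fell (30 and 0 adjusted over the list alone; median 3.38). CYP94B3 stood at 17250 ± 10590 against 38.9 ± 12.7 (8.53 ± 0.80, adjusted p = 8.24e-11) and JAZ10 at 7371 ± 3586 against 119 ± 28.2 (5.85 ± 0.68, adjusted p = 7.09e-09). AOC3 rose by 6.10 ± 0.63 and LOX3 by 5.82 ± 0.69. Of 22 abscisic acid genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), HAI1 by 8.95 ± 0.86 and RD26 by 6.16 ± 0.53. Of 26 oxidative stress genes, 18 rose (18 adjusted over the list alone), GSTU4 by 7.85 ± 0.83. Of 26 early immune genes 18 rose (19 adjusted over the list alone), PHI-1 by 5.36 ± 0.95 and WRKY40 by 4.90 ± 0.63. Tryptophan and camalexin genes rose in 13 of 17 cases with 1 lower (14 and 1 adjusted over the list alone), PAD3 by 6.07 ± 1.22. Phenylpropanoid genes rose in 12 of 18 (12 higher and 2 lower adjusted over the list alone), PAL1 by 4.49 ± 0.52. Wound and touch genes rose in 9 of 14 cases (10 adjusted over the list alone), with RRTF1 higher by 6.24 ± 1.00. Camera called these lists higher, with adjusted p = 4.22e-20 (jasmonate), 1.57e-10 (abscisic acid), 1.9e-09 (oxidative stress), 7.63e-05 (early immune), 1.02e-07 (camalexin), 1.27e-05 (phenylpropanoids) and 0.000308 (wound and touch). In the same order the adjusted p with an estimated correlation was 0.181, 0.181, 0.181, 0.718, 0.181, 0.397 and 0.512.

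Photosynthesis genes fell in OUT at 4 h in 31 of 47 cases (38 adjusted over the list alone, 22 after quantile normalization; median -0.61), LHCB2.1 of the light-harvesting complex by 1.36 ± 0.31 on the log2 scale (camera adjusted p = 2.11e-07, adjusted p = 0.91 with an estimated correlation). ICS1 did not move (0.00 ± 0.48, adjusted p = 1), and 5 of 25 salicylic acid genes rose (5 adjusted over the list alone; camera adjusted p = 0.082). Among 12 heat shock genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.231). MYB60 (-1.55 ± 0.32) and SLAC1 (-0.73 ± 0.23), of 6 guard cell markers, fell (2 adjusted over the list alone; camera adjusted p = 0.203). The largest rises were in BSMT1 (AT3G11480), whose enzyme methylates salicylic and benzoic acid, with 16190 ± 12870 against 12.96 ± 10.44 (9.808 ± 1.047, adjusted p = 1.25e-09), ILL5 (AT1G51780; 9.36 ± 1.13), the cupin gene AT4G10290 (9.27 ± 0.79) and RHD2 (9.26 ± 0.81). The largest falls were in AT1G36675 (-3.95 ± 0.70), EXPA8 (-3.816 ± 1.012), AT1G49230 (-3.72 ± 0.78) and AT5G02760 (-3.66 ± 0.80). Of the genes higher in OUT, 84.6% were also higher in IN at 4 h (3663 genes, 1505 for independent lists), and of those lower 89.4% (3878, 1494). Both areas came from the same leaf pools, so part of the excess may come from the shared leaves. Without infected replicate B, SLAC1 (-0.34, adjusted p = 0.273) and EXPA8 (-2.60, adjusted p = 0.0682) missed the threshold and 4937 genes passed, the 6 libraries alone gave 4228, and subtracting the difference at 0 h gave 4526. The split became 3572 higher and 5531 lower after quantile normalization and 3614 and 5453 with the same upper quartile.

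By 6 h the OUT response had 677 higher and 401 lower genes. Of the 677, 512 had been higher at 4 h (143 for independent lists). Jasmonate genes rose in 11 of 31 cases with 0 lower (18 and 0 adjusted over the list alone), including ST2A (AT5G07010), which sulfonates hydroxyjasmonate, at 5105 ± 2970 against 98.4 ± 30.6 (5.57 ± 0.69), CYP94B3 (5.40 ± 0.80), AT2G38240 (5.37 ± 0.82), JRG21 (4.19 ± 0.82) and JAZ10 (3.24 ± 0.68). Of 22 abscisic acid genes, 6 rose (9 adjusted over the list alone), HAI1 by 3.24 ± 0.86. Of 17 tryptophan and camalexin genes, 5 rose (9 higher and 1 lower adjusted over the list alone), the tryptophan synthase gene TSA1_AT3G54640 by 1.89 ± 0.29. None of 26 early immune genes passed (0 adjusted over the list alone). Photosynthesis genes fell in 5 of 47 cases (11 adjusted over the list alone), FBA1 by 1.36 ± 0.26 on the log2 scale. Camera gave adjusted p = 7.76e-18, 7.78e-06 and 6.38e-06 for the 3 higher lists (adjusted p = 0.181, 0.512 and 0.388 with an estimated correlation), 0.985 for the early immune list and 1.04e-09 for photosynthesis (adjusted p = 0.718 with an estimated correlation). The largest rises were in ILL5 (6.76 ± 1.13), the terpene synthase gene TPS10_AT2G24210 (6.44 ± 0.89), AT4G23680 (5.84 ± 0.89) and ST2A. The largest falls were in AT2G27420 (-3.35 ± 0.79), AT2G35637 (-3.15 ± 0.65), AT1G05767 (-3.06 ± 0.80) and NAC061 (-2.68 ± 0.77). HAI1 missed the threshold without infected replicate B (2.66, adjusted p = 0.172) or mock replicate C, AT2G27420 without infected replicate B, AT1G05767 without infected replicate A (-0.50, adjusted p = 0.225) or mock replicate B or C, and NAC061 without any 1 of the 6 libraries. Single libraries moved the count of 1078: it was 312 without infected replicate B, 564 without infected replicate C, and 711, 659 and 384 without mock replicates A, B and C. The 6 libraries alone gave 2604 genes, and subtracting the difference at 0 h left 104.

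**Figure D3:**
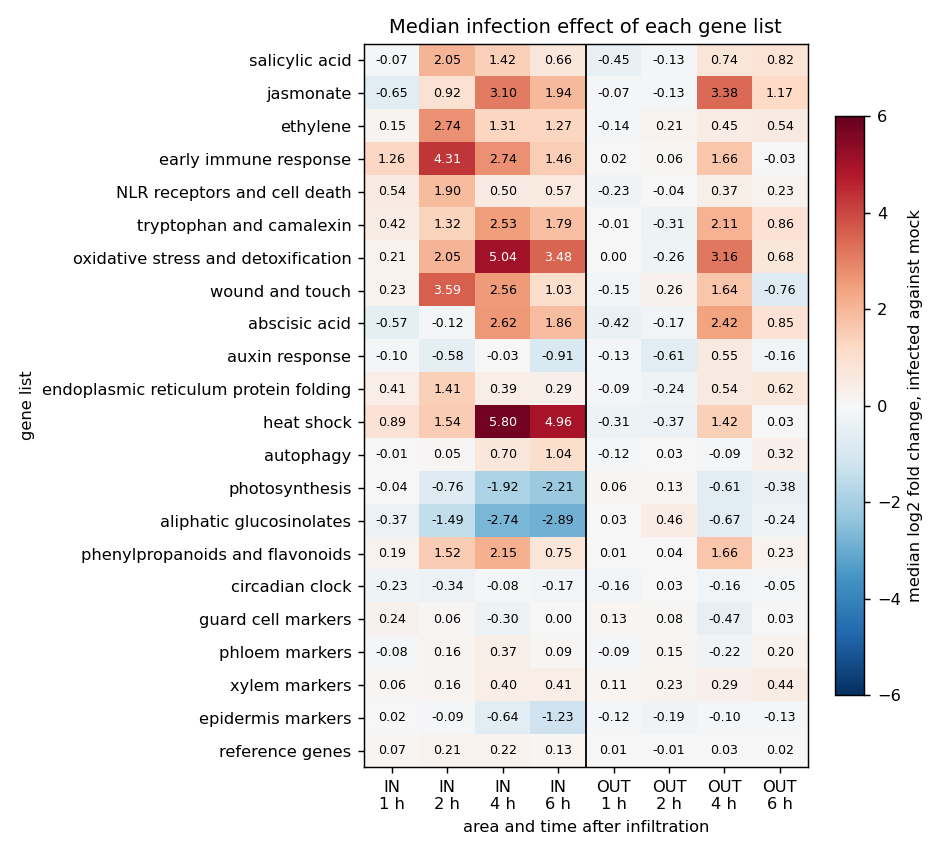
Median log2 fold change, infected against mock, of the measured members of each of 22 gene lists (y axis) by area and time (x axis), as numbers and colours. In IN the early immune list peaks at 2 h (4.31) and oxidative stress (5.04) and heat shock (5.80) at 4 h, and in OUT the jasmonate list is highest at 4 h (3.38); the medians of reference genes (IN 2, 4 and 6 h, OUT 4 h), phloem markers (IN 2, 4 and 6 h), xylem markers (IN 2 h) and protein folding (IN 4 h) change sign with the scaling, as do others within 0.1 of 0.

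The third comparison asked where the effect of infection differed between IN and OUT of the same leaves. At 0 h no gene passed limma's test (254 at an unadjusted p under 0.05). At 1 h the effect was larger in IN for 367 genes and lower for 54. IDA (AT1G68765), a peptide gene of organ shedding, had the largest difference (5.13 ± 0.96, adjusted p = 0.00473), then AT5G37490 (4.55 ± 0.92) and AT5G51465 (4.33 ± 0.93). CYP81D11 (-2.38 ± 0.59), RLP6 (-2.08 ± 0.47) and AT5G16980 (-1.93 ± 0.50) were the most negative. Early immune genes had a larger effect in IN in 7 of 26 cases (17 adjusted over the list alone; camera adjusted p = 1.45e-12, adjusted p = 0.45 with an estimated correlation). Without mock pool B, IDA (4.25, adjusted p = 0.058) and the other 5 genes named here missed the threshold, as some did without infected pool A or C or mock pool A or C, and AT5G16980 under plain empirical Bayes (adjusted p = 0.0564). The count of 421 was 108 and 206 without mock leaf pools B and A, 236 and 258 without infected pools C and A, 94 with the 2 areas of a leaf pool treated as unrelated, 180 with the 6 pools alone and 2 after the difference at 0 h was subtracted.

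At 2 h the effect was larger in IN for 5222 genes and lower for 5036. All 26 early immune genes had a larger effect in IN (26 adjusted over the list alone; camera adjusted p = 1.3e-14, adjusted p = 0.45 with an estimated correlation), as had 20 of 21 genes of receptors and cell death (20 adjusted over the list alone). FRK1 differed by 6.06 ± 1.04. Without the 2 mock libraries that lay apart at 2 h the difference was 1.86. That value rests on mock pool C alone, since pools A and B each lost a library. ICS1 differed by 3.399 ± 0.426 and RPM1 by 2.07 ± 0.35. The largest differences were in AT2G44370 (7.98 ± 1.34), MMP (7.87 ± 0.81) and AGL50 (7.41 ± 0.81). The most negative were in AT5G66580 (-4.32 ± 0.51), AT3G08660 (-4.12 ± 0.72) and GIS (-4.07 ± 0.60). Quantile normalization gave 3995 larger and 6111 lower, the same upper quartile 3870 and 6891, and the 6 pools alone 6371 genes.

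At 4 h heat shock genes separated the areas and jasmonate genes did not follow the same direction. The effect was larger in IN for 11 of 12 heat shock genes (12 adjusted over the list alone; median 3.76), AT1G52560 by 6.87 ± 1.06 and HSP17.6A by 5.14 ± 1.23. It was larger also for 12 of 17 autophagy genes (13 adjusted over the list alone), ATG8H by 2.35 ± 0.29, and for 16 of 26 oxidative stress genes (17 adjusted over the list alone), UGT73B5 by 3.62 ± 0.37. All 47 photosynthesis genes had a lower effect in IN (47 adjusted over the list alone), RBCS1B by -2.31 ± 0.30. Camera gave adjusted p = 0.000121, 0.000122, 4.17e-05 and 2.25e-19, and adjusted p = 0.491 for each with an estimated correlation. Among 31 jasmonate genes the effect was larger in IN for 2 and lower for 9 (1 and 8 adjusted over the list alone), with CYP94B3 at -2.87 ± 0.68, LOX3 at -2.19 ± 0.68, CYP94C1 at -1.80 ± 0.58 and JAZ10 at -1.76 ± 0.70 (adjusted p = 0.0408), against VSP2 at 1.76 ± 0.58; camera did not call the list (adjusted p = 0.102). After quantile normalization 2 were larger and 14 lower. These are differences of effects, and a lower effect in IN need not be a lower level there, since mock levels differed between the areas. The geometric mean of the count plus 1 of CYP94B3 at 4 h was 17890 in infected IN and 14220 in infected OUT tissue. In mock IN and OUT tissue it was 354 and 38.4. For JAZ10 it was 5012 and 6773 in infected IN and OUT tissue, and 294 and 117 in mock. The differences of JAZ10 and CYP94C1 missed the threshold without mock leaf pool B (-1.14, adjusted p = 0.226, and -1.36, adjusted p = 0.0862) and without infected pool B. That of JAZ10 missed it also without pool A of either treatment and under plain empirical Bayes (adjusted p = 0.0531), that of LOX3 without mock pool A (-1.84, adjusted p = 0.0547), that of VSP2 without mock pool C (1.44, adjusted p = 0.0799) and that of the transcription factor gene SPL13B without mock pool B (-7.22, adjusted p = 0.0561). ICS1 differed by 2.52 ± 0.43 and AT5G17760 by 1.22 ± 0.34 (adjusted p = 0.0048). Over all genes 4383 had a larger and 5239 a lower effect in IN (3416 and 6478 with the same upper quartile). The largest differences were in AT1G13520 (7.34 ± 1.38), AT1G52560 and SVL3 (6.62 ± 0.93), and the most negative in SPL13B (-8.61 ± 2.70), which has a near-identical copy, AT5G38130 (-4.46 ± 1.13) and the plasmodesma gene PDLP3 (-4.34 ± 0.48). Subtracting the difference at 0 h left 6139 genes.

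At 6 h, 4767 genes had a larger and 5082 a lower effect in IN. Heat shock genes were larger in IN in 11 of 12 cases (11 adjusted over the list alone; median 4.95), HSP17.6A by 7.59 ± 1.23 and HSP17.4 by 6.85 ± 1.15, and early immune genes in 17 of 26 (17 adjusted over the list alone), PER4 by 6.49 ± 0.89 and WRKY6 by 3.84 ± 0.37. All 47 photosynthesis genes were lower in IN (47 adjusted over the list alone), LHCB3 by -2.06 ± 0.20. Camera adjusted p was 1.67e-05, 7.96e-05 and 4.71e-28 (adjusted p = 0.45, 0.711 and 0.45 with an estimated correlation). The largest differences were in AT1G15385 (7.72 ± 0.94), GEX3 (7.71 ± 0.99) and HSP17.6A. The most negative were in CYP81F4 (-5.590 ± 1.048), AT5G36790 (-4.50 ± 0.89) and the protease gene AT4G11320 (-4.39 ± 0.90). Subtracting the difference at 0 h left 6195 genes.

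**Figure D4:**
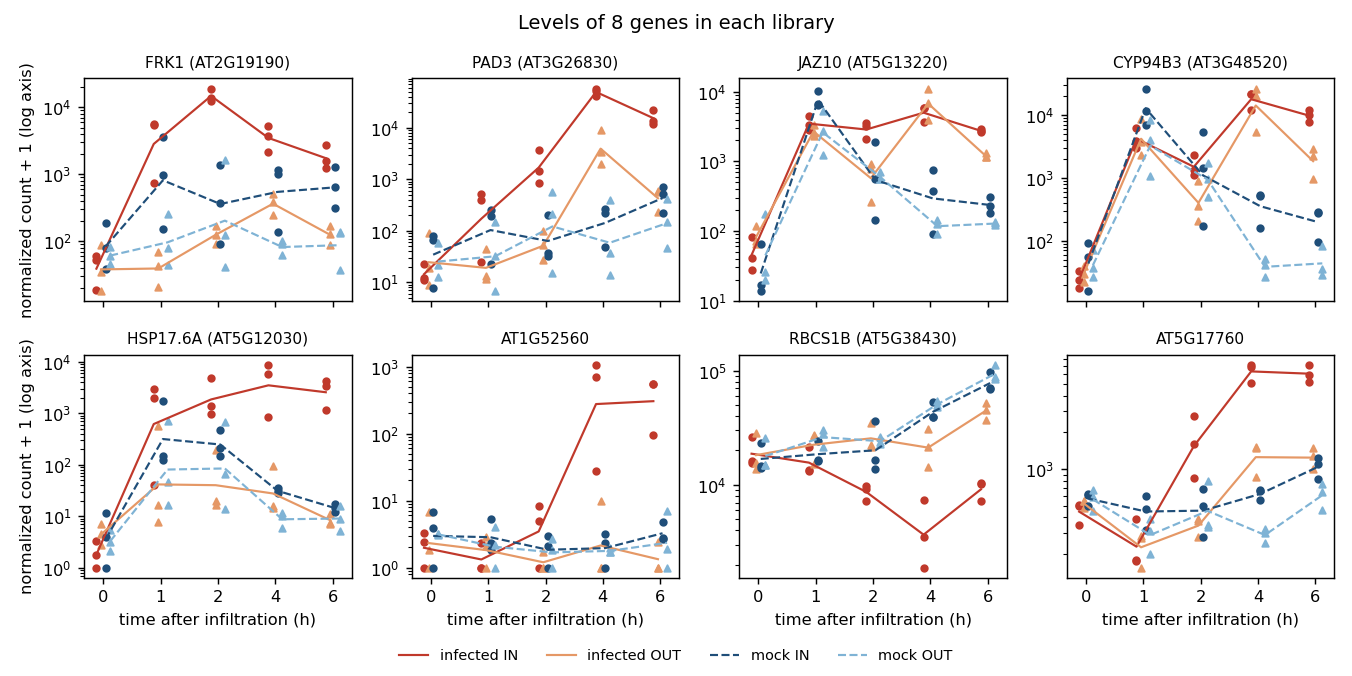
Normalized counts plus 1 on a log y axis against hours after infiltration (x axis) for 8 genes, 1 point per library, with lines through the geometric means of the 3 libraries of each group. At 4 h the line of AT1G52560 stands at 276 in infected IN and 2.14 in infected OUT tissue, and that of CYP94B3 at 17890 and 14220.

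Genes whose rise stayed in the infiltrated area were then counted. A gene entered where it rose by at least 2 on the log2 scale in IN at 4 and 6 h, the rise exceeded that in OUT by the test of the difference at both times, and the OUT fold change stayed under 1 on the log2 scale at 1, 2, 4 and 6 h. These rules gave 271 genes. Ranked by the smaller of the 4 and 6 h rises, the first 10 were the small heat shock genes AT1G52560 and ATHSP22.0, GEX3 (AT5G16020), the cellulose synthase-like gene CSLD1 (AT2G33100), AT1G13520, AT5G25920, the bZIP factor gene TGA10 (AT5G06839), the cysteine protease gene CP1_AT4G36880, ENSRNA049757586-T1 and AT1G04047. At 4 h GEX3 stood at 262 ± 108 in infected IN against 2.99 ± 3.53 in mock IN and 2.88 ± 2.06 in infected OUT tissue, CSLD1 at 262 ± 31.8 against 3.56 ± 1.84 and 6.03 ± 3.03, and TGA10 at 67.2 ± 56.2 against 0.333 ± 0.577 and 0.9886 ± 0.9005. AT5G17760 was not among them, since its OUT rise at 4 h was 2.13 ± 0.34 (adjusted p = 4.54e-06). Genes of the surrounding area, as they are called here, numbered 328. They rose in OUT by at least 1 on the log2 scale at 4 or 6 h, and by more than in IN by the test of the difference. Their rise in IN was not limited, so the rule does not confine them to OUT, and the first 5 rose in IN too. The glycosyltransferase gene UGT76E12 (AT3G46660; OUT 9.07 ± 0.97, IN 6.56 ± 0.97 at 4 h), CYP94B3, CYP94B1 (AT5G63450; 8.28 ± 0.76 and 4.50 ± 0.76), AT2G30830 (8.24 ± 0.76 and 5.37 ± 0.76) and AT1G69480 (8.07 ± 0.82 and 5.47 ± 0.82) led them. Without experiment C the first count was 162, and without experiments A and B the second was 136 and 117.

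The mock libraries show what time and infiltration alone did. From 0 h, 15148 genes changed in mock IN (73.7% of those tested) and 12228 in mock OUT tissue (59.5%). At single times 35.3 to 48.0% of genes were called in mock IN and 24.0 to 44.0% in mock OUT, split nearly evenly between higher and lower. All 20 circadian clock genes passed the F-test in both areas. By 6 h in IN the morning genes CCA1 and LHY had changed by -9.38 ± 0.34 and -9.08 ± 0.49 on the log2 scale and the evening gene ELF4 by 7.165 ± 1.095, and in OUT the changes were -9.28 ± 0.34, -8.65 ± 0.49 and 7.058 ± 1.095. In the infected against mock comparison camera called the clock list in IN at 1 h only (1 of 20 lower, also 1 adjusted over the list alone; adjusted p = 0.0066, adjusted p = 0.556 with an estimated correlation) and not in OUT. Jasmonate genes rose at 1 h after mock infiltration, 30 of 31 in IN (median 5.04) and 31 of 31 in OUT (median 3.73), AT2G38240 from 19.1 ± 15.8 to 16570 ± 5090 (10.01 ± 0.81) and JAZ10 from 31.0 ± 29.3 to 7780 ± 2048 (8.28 ± 0.68) in IN. Early immune genes rose in 18 of 26 cases with 0 lower in IN at 1 h, and in 1 case with 8 lower in OUT. Wound and touch genes passed the F-test in all 14 cases in both areas. CML39 rose at 1 h by 4.59 ± 0.73 in IN and 4.55 ± 0.73 in OUT, while the touch gene TCH4 fell by 3.96 ± 0.57 and 4.31 ± 0.57 on the log2 scale by 4 h. Genes of endoplasmic reticulum protein folding rose in 7 of 17 cases in IN and 8 in OUT at 1 h, in 15 in both areas at 2 h (1 lower in OUT) and in 16 in both at 6 h, and aliphatic glucosinolate genes rose in 10 of 12 cases in IN and 9 in OUT at 4 h.

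Between mock areas of the same leaves, averaged over the 5 times, 3394 genes were higher in IN and 3325 lower, 469 and 136 of them by at least 2-fold. Together they were 32.7% of the genes tested. Early immune genes were higher in IN in 23 of 26 cases (median 0.97) and oxidative stress genes in 15 of 26 with 1 lower (median 0.79). All 47 photosynthesis genes (median -0.24; 17 after quantile normalization) and all 12 aliphatic glucosinolate genes (median -0.79) were lower in IN. With the same upper quartile the split was 2641 higher and 4573 lower, 2558 genes passed with the 2 areas of a leaf pool treated as unrelated, and 2863 and 3998 without experiments A and C. Leaving out the 2 mock libraries that lay apart at 2 h left mock pool C alone at that time, so no count is given for that fit.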

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

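The tests of the difference between 4 and 6 h, the counts of opposite directions and the test of each explanation were chosen after the result was seen; the test of the difference between areas was planned.

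The infection effect in OUT differed between 4 and 6 h for 2095 genes, by a test of the difference itself. The signed effect was higher at 4 h for 1309, of which 1266 were called higher at 4 h, and lower for 786, of which 714 were called lower at 4 h. The signed effect was higher at 4 h for 15 of 31 jasmonate genes, 11 of 18 phenylpropanoid and flavonoid genes, 10 of 22 abscisic acid genes and 9 of 14 wound and touch genes. The effect in IN differed between the same times for 2248 genes. The signed effect was higher at 4 h for 974, of which 815 were called higher at 4 h, and lower for 1274, of which 1141 were called lower at 4 h. For the same lists in IN it was higher at 4 h for 5, 5, 8 and 4 genes.

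A few genes went opposite ways in the 2 areas, with the difference tested as well. At 4 h there were 71, of which 47 were higher in IN and lower in OUT and 24 the reverse. CYP82C2 changed by 2.36 in IN and -2.58 in OUT on the log2 scale, AT1G09987 by 3.74 and -1.89, and APT5 by -2.13 and 1.42. At 6 h there were 11 such genes, among them HDG8 (1.83 and -2.37) and LBD16 (2.18 and -1.49). These names were chosen after their values were seen.

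That OUT had 8667 called genes at 4 h and 1078 at 6 h could be technical. Carried-over infiltrated tissue would bring every strongly raised IN transcript along. Yet over the 570 genes with the largest IN rises at 4 h the OUT rise was 0.025 of the IN rise at the 10th percentile. That argues against carried tissue as the whole cause. The share had a median of 0.126 and a 90th percentile of 0.581 at 4 h, and a median of 0.021 over 343 such genes at 6 h. A part played by carried tissue was therefore not excluded. Quantile normalization left the 4 h count 7.271 times the 6 h count, which argues against the scaling, and the lowest 4 h count with 1 library left out, 4937, argues against a single library at 4 h. Fits to the 2 groups alone gave 4228 and 2604 genes, so the size of the contrast depends on the shared estimate of spread. A rise that fades with time after infection remains an open biological explanation, untested beyond these values.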

How the results depend on the processing

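The alternative without the 2 mock libraries at 2 h was added after the data were seen, and the others were planned. Both other pseudocounts, quantile normalization, the same upper quartile and the replicate block left all 23 counts within 1.5 times. With the replicate block, 691 genes passed in IN at 1 h, 9130 in OUT at 4 h and 1377 in OUT at 6 h. The block fits 1 offset per experiment over all groups and times. It does not pair infected with mock libraries of 1 experiment at 1 time. Quantile normalization shifted the median of all genes to -0.17 in IN at 2 h, -0.13 in IN at 4 h and -0.14 in OUT at 4 h, and the same upper quartile to -0.23, -0.25 and -0.14, so falls of that size depend on the scaling.

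Without the filter 1 gene passed in IN at 0 h and 2 in OUT at 0 h. With the areas unpaired (no replicate block) 94 genes passed for the area difference at 1 h and 2558 between the mock areas. With an estimated correlation camera called 0 lists in IN, 0 in OUT and 0 for the difference. Fits to the 2 groups compared alone gave 0 genes in IN at 1 h, 6209 in IN at 2 h, 4228 in OUT at 4 h, 2604 in OUT at 6 h, and 180 and 6371 for the area difference at 1 and 2 h; such fits have few degrees of freedom. Subtracting the difference at 0 h, which adds its error, gave 110 in IN at 1 h, 4526 and 104 in OUT at 4 and 6 h, and 2, 6139 and 6195 for the area difference at 1, 4 and 6 h. ACT2 in IN at 4 h reversed to -0.447 after quantile normalization. Beyond these constructions the cause was not tested.

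Leaving out 1 library at a time gave 0 to 1 genes in IN at 0 h, 197 to 822 in IN at 1 h, 4937 to 9822 in OUT at 4 h and 312 to 914 in OUT at 6 h. Leaving out leaf pools gave 0 to 1 and 108 to 579 for the area difference at 0 and 1 h. Leaving out experiments gave 2863 to 5149 between the mock areas, 162 to 297 genes confined to IN and 117 to 403 of the surrounding area. Of 241 gene results, 212 kept their direction and call under every alternative run for single genes; fits to the 2 groups alone, subtraction of 0 h and unpaired areas were run for counts only. Plain empirical Bayes cannot be applied to camera, and a count model was not run because whole reads could not be recovered. Depth limits genes near the minimum of 10.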

Other observations

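The comparison of the OUT response with mock infiltration and the test of reference genes were set before their results were seen; the other tests here, including the splits, were chosen after.

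The 2 mock libraries that lay apart at 2 h may have exchanged labels. Mock OUT replicate B scored 3.485 on the area score, near the mock IN libraries, and mock IN replicate A scored 0.379, near mock OUT, so each has a partner out of place. Weak infiltration of replicate A alone would leave OUT replicate B in place, but it exceeded the other mock OUT libraries by 3.041. Mock OUT replicate A (0.444) and mock IN replicate B (3.870) scored as labelled, so an exchange would have moved the experiment letters too. Mock IN replicate A correlated at 0.537 with infected A and 0.125 with infected B (difference 0.412), which leans against an exchange. Mock OUT replicate B correlated at 0.334 with infected A and 0.287 with infected B, which leans slightly the other way. The own letter was highest in 19 of 30 mock libraries only, so the letters do not decide it and the exchange stayed open. The libraries were kept as the labels give them.

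The OUT response at 4 h correlated across 20560 genes with the change after mock infiltration in IN at 1 h (Pearson r 0.674) and with the infected IN response at 6 h (0.721) and at 2 h (0.566). Genes are not independent replicates. The values do not decide whether the OUT response is the early response to infiltration, since the first value lies between the other 2: the highest would have been in favour and the lowest against.

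Reference genes called in infected IN tissue might reflect scaling. After quantile normalization 5 of 12 were called at 2 h, 2 of them higher, and 8 at 4 h, 3 of them higher. Calls in both directions are not what a common shift would give, which argues against scaling as the whole cause. The number and direction of calls did depend on scaling. At 4 h most calls were higher as deposited and lower after quantile normalization.

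For comparisons of 3 against 3, 10 splits cannot give a share under 0.05. In IN the real counts were 0, 597, 9634, 14225 and 12154 at 0, 1, 2, 4 and 6 h, against 11, 2187, 2759, 694 and 1 for the highest other split. In OUT they were 0, 0, 0, 8667 and 1078 against 3, 86, 1, 1 and 1, and for the area difference 0, 421, 10258, 9622 and 9849 against 0, 71, 1812, 0 and 0. At 1 h in IN 2 splits gave as many genes as the real one, and the other, infected A and C with mock A against the rest, called 2187 genes. It puts both libraries of experiment A on one side and both of B on the other. This points to the experiments as a structure of these samples. With the replicate block 691 genes passed, but that block holds 1 offset per experiment over all times. Such an offset does not remove differences between experiments at 1 h alone. Of the 3 other splits that part infected and mock of every experiment, as the real one does, the highest gave 2 genes there. Over all 15 comparisons such splits gave at most 2, so the larger counts came from splits with both libraries of an experiment on one side.

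Chance could be excluded for the mock counts across time, where only the real 1 of 100 splits gave as many (15148 and 12228 against 10537 and 2212). Between mock areas 2 of 100 splits gave as many, the real one included. The other gave more genes than the real labels (7475 against 6719), so the count is not particular to the real labels. Why was not tested. For genes confined to IN (271 against 0) and of the surrounding area (328 against 40) only the real 1 of 40 splits gave as many. These splits remove the infection effect, so they do not test whether a rise kept to 1 area, or was larger there, by chance. List calls in IN were 51 against 46 in the highest other of 40 splits. Some of the 51 came at 0 h, when no gene passed, and camera called 0 lists in IN with an estimated correlation. For these calls, too, chance was not excluded. It could not be excluded for list calls in OUT, where 23 of 40 splits gave as many as the real 28 (highest 50), nor for the area difference, where 4 of 40 did (37, highest 42).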
